A study of Mus musculus with 51 samples.

How the data were processed

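Fluorescence-sorted CD8+ T-cell subsets from AT3-OVA mouse mammary tumors and spleens were profiled in 51 libraries of 18 groups. Per the labels' protocols, 10 ng of total RNA entered QuantSeq 3' mRNA-Seq FWD preparation, the libraries were sequenced as 75 bp single-end reads on a NextSeq500, and the number of reads per library was not used here. Alignment with HISAT2 to mm10 and counting with HTSeq are named in the submitters' processing notes, without versions. The authors deposited 2 tables of normalized values, 1 of untreated libraries and 1 of the ICB libraries; the normalization method is not stated in the labels. The values deposited by the authors were read as log2 because they include negative numbers and a span that linear values would not have. The log base is an inference, and fold changes depend on it. Counts were not analysed here, so library depth, counting error, detection limits and duplicated libraries could not be examined.

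Each table was tested for the number of independent directions among its libraries. The untreated table, with 43 libraries, had a rank of 32 after centring each gene, where 42 is the most possible, and the residuals from the 15 group means had a rank of 18 where 28 is the most possible. The ICB table had a rank of 4 where 7 is the most possible, and a residual rank of 2 where 5 is the most possible. Such a loss, of 10 and 3 directions, is the form left when estimated factors of unwanted variation have been subtracted from a table; the labels record no such step. Levels in the untreated table are not abundances: gene means ran from -28.0 to 39.4, and Gapdh, an abundant transcript, had a mean of 4.50 where Foxp3, a transcript of regulatory T cells, had 23.7. Differences within a gene were therefore used. Levels still entered limma's trend option, the filters and floors among the alternatives and the median-level condition of the rule for named genes, all fixed before the data were examined, and say little about abundance in this table. The 2 tables were never mixed in a fit, so the effect of ICB itself was not tested.

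For each table limma 3.58.1 in R 4.3.3 fitted group means to the deposited values, with moderated tests (trend and robust options, statmod 1.5.0) of the contrasts and Benjamini-Hochberg adjustment over all genes of the table. A gene was called at an adjusted p below 0.05. All groups of a table shared 1 estimate of the spread. Pooled tumor comparisons weighted the weeks equally. Residual degrees of freedom were multiplied by 0.6429 in the untreated table and by 0.4 in the ICB table, the ratio of residual rank to residual degrees of freedom, and residual variances were divided by the same ratio. This step, and the absence of a filter on low values in the reported counts, were departures from the plan made after the tables were seen: the plan had ordinary degrees of freedom and a filter at a log2 value of 0 in at least 3 libraries (2 in the ICB table), which has no meaning where levels are not abundances. Design-based counts use the unreduced degrees of freedom. The comparisons, gene lists, naming rule and the other alternatives were chosen before the data were examined.

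The tests were tested on simulated data of each table's shape, with 200 changed genes and 5 simulated tables for each setting. For DP against DN in a table of the untreated shape with 10 directions removed, 12.2% of unchanged genes had p below 0.05 with design-based degrees of freedom and 5.22% with reduced ones, at which 53.4%, 89.6% and 98.8% of genes changed by 0.5, 1 and 2 were recovered. For DP against SP in a table of the ICB shape the shares were 24.2% and 5.56%, and 0.895%, 17.0% and 49.7% of such genes were recovered. Where unwanted factors had been added before removal, the reduced degrees of freedom gave 10.2% and 14.0%; adjusted p-values are then too small. The labels do not say whether replicates are single animals or pools. The p-values therefore measure spread between these samples, and only the part of it that the deposited values still hold.

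Gene lists numbered 23: tissue-resident memory, circulating memory, exhaustion and checkpoint, cytotoxic, cytokines and chemokines, NK receptors, TGF-beta response, chemokine receptors and integrins, proliferation, interferon-stimulated, immediate-early and stress, glycolysis and hypoxia, oxidative phosphorylation, lipid uptake and oxidation, ribosomal proteins, T-cell identity, and markers of myeloid cells, B cells, tumor epithelium, stroma and endothelium, CD4 and regulatory T cells, gamma-delta T, NK and NKT cells, and erythroid cells and platelets. Some genes are members of several lists. Each list was tested with camera at a preset inter-gene correlation of 0.01 and again with the correlation estimated, with adjustment over the lists of a comparison; of 345 such tests 161 passed with the preset and 32 with the estimated correlation. A rotation test, fry, which asks only whether a list's genes move one way on balance, passed 222. Median and mean differed in sign in 30. Camera and fry were run with the unreduced degrees of freedom, so their p-values lack the correction made for single genes and can be too small. The estimated correlation came from residuals of rank 18 in the untreated table and 2 in the ICB table. A score is the mean over list members of the log2 value minus the gene's mean over its table.

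The rule for named genes took Itgae and Cd69, up to 4 members of each list with the smallest p-values, and the 6 genes with the largest called difference in each direction that lay above the median level and had the same sign at every week, or no overlap between the libraries of the groups (3 against 3 libraries separate by chance in 10% of genes). Gene models without names, pseudogenes, mitochondrial genes and receptor variable segments were skipped. The examples printed are a part of the genes so taken, picked after their values were seen and mostly from those whose call held on leaving out any 1 library, so the examples are steadier than the genes the rule took. Some genes are not reported here.

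Alternatives were other scalings (quantile normalization, median rescaling), raised floors, filters, array weights, a 2-fold minimum, fits of only the groups compared, a replicate block, the run of library codes as a term, single weeks and leaving out each library. The library codes in the labels fall into runs of 5 to 42, 46 to 61 and 72 to 75; DN libraries lie in the later runs and the labels do not call the runs batches. Added after the data were seen were design-based degrees of freedom, a fit without week 1, week 6 against week 2, and DP against DN within codes 46 to 61. Other splits of the samples were drawn up to 100 times. Coordinates are those of GENCODE M21 on GRCm38. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. HTSeq's strand setting and its treatment of overlapping genes are not stated, so genes that overlap or are near-identical, such as members of the granzyme and Klr families, carry that uncertainty.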

Results

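CD8+ T cells were sorted by flow cytometry from AT3-OVA tumors of mice and from spleens, and their mRNA was profiled by QuantSeq, a 3' tag method that reads 1 site near the end of each transcript. AT3-OVA is a mouse mammary carcinoma line engineered to carry ovalbumin as a model antigen. Tumor cells were divided by CD103, the integrin subunit that holds T cells to E-cadherin on epithelium, and CD69, a surface protein that retains T cells in tissue. The CD103+CD69+ cells are called DP here, the CD103-CD69+ cells SP and the CD103-CD69- cells DN. DP libraries numbered 3, 4, 3 and 3 at weeks 1, 2, 4 and 6. SP libraries numbered 3, 3, 2 and 3 and DN libraries 2, 3, 3 and 2 at the same weeks. Spleen, titled Cntrl Spleen in the labels, gave 3 libraries each of naive cells and of the subsets labelled CM and EM. A separate table held tumors on day 40 under immune checkpoint blockade (ICB), with 3 DP, 3 SP and 2 DN libraries. The untreated table had 43 libraries and 10560 genes, and that of ICB had 8 libraries and 13458 genes. The deposited values were already normalized and logged, so the read depth of each library is unknown, and each value below is a difference of means on that scale, taken as log2, or a share of the genes. The libraries of each table varied in fewer independent directions than their number allows. The main counts, unlike the list tests, use residual degrees of freedom reduced to match. The count with the larger number that the design alone would give stands beside each as the design-based count.

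Itgae, which encodes CD103, was highest in DP in the untreated tumors, but also differed between the 2 subsets sorted as CD103-. Its value was 1.11 higher in DP than in SP (SE 0.28, 13 against 11 libraries, adjusted p = 0.0316), 2.82 higher in DP than in DN (adjusted p = 2.8e-06) and 1.71 higher in SP than in DN (adjusted p = 0.000583). The DP value exceeded the SP value at all 4 weeks, by 0.81, 1.38, 0.83 and 1.42, and passed the test at none of them alone. The call between DP and SP was lost on leaving out any 1 of 7 libraries: SP week 1 replicates 1 and 2, SP week 2 replicate 1, DP week 4 replicate 2, SP week 4 replicate 1, DP week 6 replicate 3 or SP week 6 replicate 3, with adjusted p between 0.0505 and 0.1. Cd69 was 0.78 higher in DP (adjusted p = 0.0059) and 0.82 higher in SP (adjusted p = 0.00651) than in DN, and differed by -0.03 between DP and SP (adjusted p = 0.949), both of which were sorted as CD69+. Itgae lies on chromosome 11 from 73090583 to 73147446 on the plus strand and Cd69 on chromosome 6 from 129267325 to 129275436 on the minus strand of GRCm38. In the spleen, where naive CD8 T cells are known to carry CD103, Itgae differed from naive cells by -2.41 in the subset labelled EM (adjusted p = 0.00304) and by -2.79 in the subset labelled CM (adjusted p = 0.00135).

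**Figure D1:**
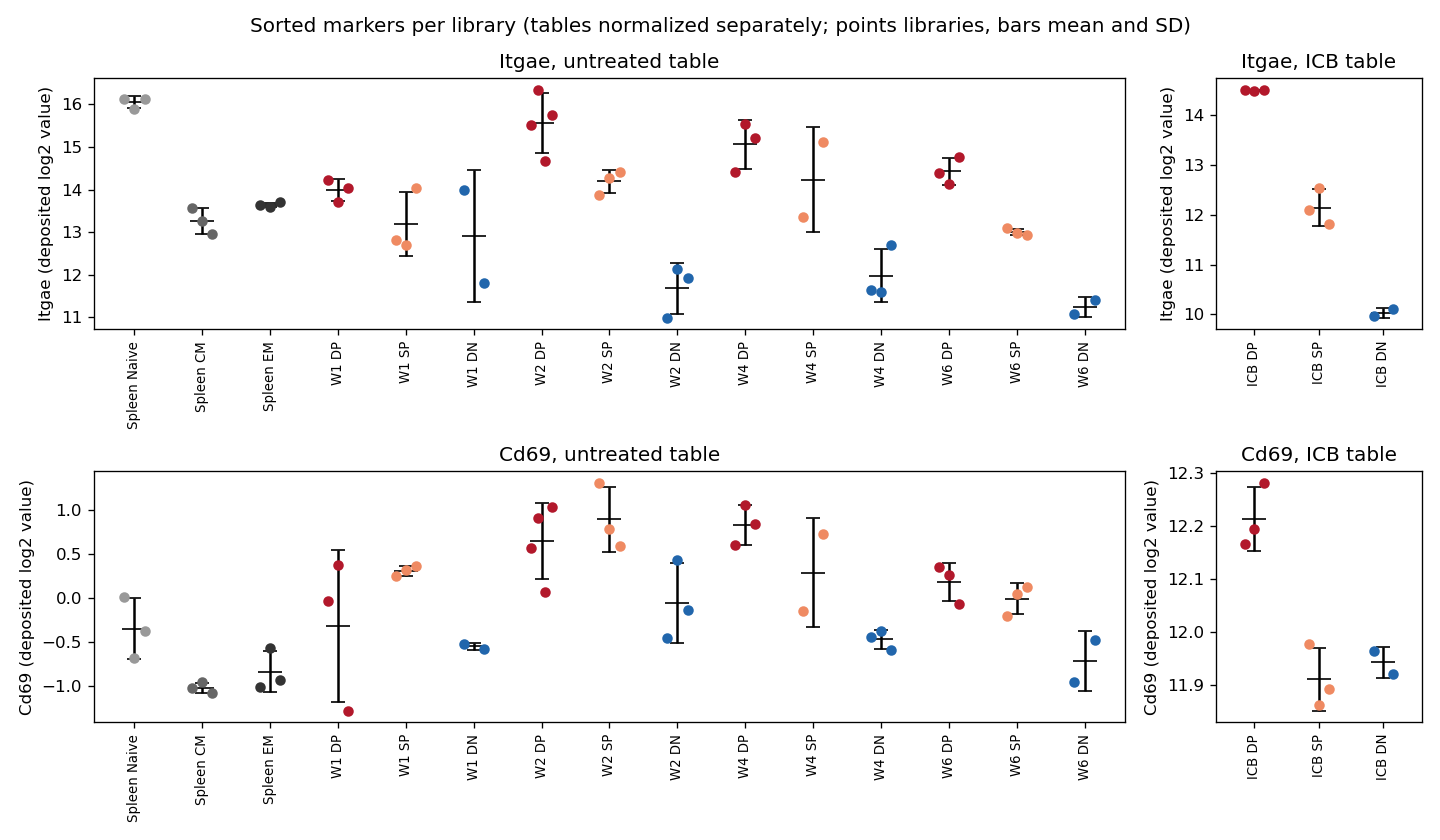
Deposited log2 values of Itgae and Cd69 in each library, by group, with points for single libraries and bars for group means. Itgae in DP lay above DN by 2.82 on average over the 4 weeks of the untreated table, and naive spleen cells had the highest group mean of that table.

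The comparison of DP with SP asked what distinguishes CD103+ from CD103- cells among the CD69+ cells of the untreated tumor. Genes of T-cell identity, which encode the receptor complex and its proximal kinases, were lower in DP for 12 of 15 measured members, with Cd8a lower by a log2 difference of -0.54 (adjusted p = 0.000228) and Zap70 by -0.36 (adjusted p = 0.00064). Checkpoint and exhaustion genes were lower for 8 of 22 members and higher for none. Pdcd1, which encodes the inhibitory receptor PD-1, differed by -1.26 (adjusted p = 0.000438), Tox, a transcription factor of exhausted cells, by -0.62 (adjusted p = 0.00606), and Cxcr6, a chemokine receptor of tissue T cells, by -0.78 (adjusted p = 0.000489). Cytokine and chemokine genes were lower for 5 of 15 members, among them Ifng (-1.05), Ccl3 (-1.09) and Ccl4 (-0.91). Without week 1, limma called 0 of the 15 cytokine genes (7 adjusted over the list alone) and 2 of the 22 checkpoint genes, with medians of -0.28 and -0.27. In the cytotoxic list 4 of 15 members were lower, including Fasl, a death ligand (-0.87, adjusted p = 1.54e-05), and Gzmk (-1.29, adjusted p = 0.0171), and none was higher. The median of that list was -0.93 at week 1 but 0.04, 0.36 and 0.15 at weeks 2, 4 and 6, and without week 1 it was 0.16 with 1 member lower. The costimulatory receptor gene Cd40 (+0.96, adjusted p = 0.0122) was among the genes higher in DP. Which cells expressed it was not tested, and the median of the myeloid genes was higher in DP too, as given below. The list of tissue-resident memory genes had 3 of 26 members higher, 3 lower and a median of -0.01 (0.03 under quantile normalization and under median rescaling), in which opposite weeks offset each other. It was -0.62 at week 1 and 0.03, 0.17 and 0.27 at weeks 2, 4 and 6, and 0.21 without week 1.

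By camera with a preset correlation, the T-cell identity list passed (adjusted p = 4.62e-18, and 0.00388 with an estimated correlation), as did the cytokine list (adjusted p = 0.00128, and 0.0452 with an estimated correlation) and the checkpoint list (adjusted p = 9.81e-10, but adjusted p = 0.0643 with an estimated correlation). The cytotoxic list did not pass (adjusted p = 0.459). With adjustment over each list alone, 15 of 15 identity, 13 of 22 checkpoint, 6 of 15 cytokine and 4 of 15 cytotoxic genes were lower in DP. Genes of myeloid cells moved the other way: their median was 0.48 higher in DP, with 0 of 12 members past limma's test over all genes, 3 adjusted over the list alone and a camera adjusted p of 2.74e-06 (adjusted p = 0.283 with an estimated correlation). In all, 368 genes passed, 81 higher and 287 lower in DP, with a design-based count of 1554; 1890 had an unadjusted p below 0.05. The split was 106 higher and 203 lower after quantile normalization, and 122 and 188 after median rescaling. A replicate block, a pairing that no label names, gave 163 genes, and a fit of only the groups compared gave 191. The difference came mostly from week 1, at which 1835 genes passed. Every week was tested against 1 shared spread, although DP at week 1 had the largest median SD over genes of all groups. That SD was 0.289 in DP and 0.167 in SP at week 1, so tests with DP at week 1 can call too many genes. At weeks 2, 4 and 6, limma called 0, 15 and 0 genes (design-based 53, 654 and 125, and 677, 1355 and 729 with an unadjusted p below 0.05), and 44 genes passed over those 3 weeks together, of which 11 were higher. At week 1 the mean T-cell identity score was -0.77 in DP and -0.07 in SP, and the mean epithelial score 2.27 and 1.75. Without week 1, 12 of 15 identity genes still passed adjusted over the list alone, although none did over all genes.

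**Figure D2:**
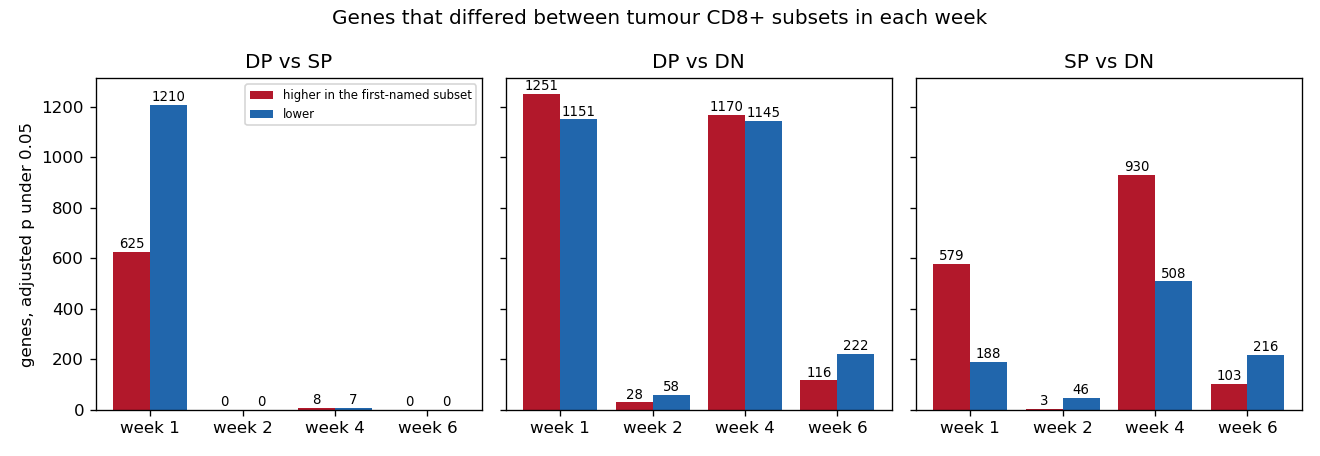
Number of genes with an adjusted p below 0.05 in each pair of tumor subsets at each week, higher and lower genes drawn apart. DP against SP gave 1835 genes at week 1 and 0 at weeks 2 and 6, while DP against DN gave 2402, 86, 2315 and 338 genes at weeks 1, 2, 4 and 6.

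The comparison of DP with DN set the cells with both residency markers against the tumor cells with neither. Genes of circulating memory and lymph node homing were lower in DP for 16 of 19 members, led by S1pr1, the receptor through which T cells leave tissue (-2.29, adjusted p = 3.86e-06), Klf3 (-1.65, adjusted p = 2.82e-06) and Eomes, a memory transcription factor (-1.37, adjusted p = 6.45e-06). The cytotoxic list did not pass (adjusted p = 0.144, and 0.327 with an estimated correlation): 4 of its 15 members were lower and 6 higher, the latter including Gzmc by 4.38 (adjusted p = 2e-05), Gzma by 1.57 (adjusted p = 7.71e-05) and Gzmb by 1.98 (adjusted p = 0.000233). Tissue-resident memory genes were higher for 11 of 26 members and lower for 2, with Zfp683, which encodes the residency factor Hobit, higher by 0.92 (adjusted p = 0.00554). Week 1 went the other way, with medians of -0.41 for the resident, -0.64 for the NK-receptor and -0.86 for the cytotoxic list. The epithelial median was 3.69 at week 1 and -0.77, -0.04 and -1.70 at weeks 2, 4 and 6. The resident list gave 0.58, 1.09 and 0.65 at weeks 2, 4 and 6. At week 1 Zfp683 differed by -1.18 and Gzma by -0.06. Chemokine receptor and integrin genes were lower for 11 of 19 members, including Itga4 (-1.21, adjusted p = 7.31e-08), and Itgae was the 1 member that was higher. NK-receptor genes were higher for 7 of 12 members, with the signalling adaptor Fcer1g higher by 1.97 (adjusted p = 1.04e-05), and the regulatory T-cell factor gene Foxp3 was higher by 1.82 (adjusted p = 7.96e-05). Immediate-early and stress genes were higher for 9 of 22 members, Nfkbia by 0.80 (adjusted p = 8.76e-05), and interferon-stimulated genes were lower for 7 of 22, Ifit3 by -0.54 (adjusted p = 0.00194). The interferon median was -0.71 at week 1 and -0.11, -0.0007 and -0.17 later, and -0.05 without week 1, with 5 members lower and 1 higher. Markers of other cells also differed. The gamma-delta T, NK and NKT list moved with the NK receptors, with which it shares a gene: its medians were -0.97, 1.84, 1.18 and 1.98 at weeks 1, 2, 4 and 6, with 1 of 2 members higher over all weeks (adjusted p = 0.296 for the list with an estimated correlation). Erythroid genes were lower in 2 of 2 members, with medians of 1.89, -0.51, -5.62 and -2.73 at the 4 weeks, and stroma genes in 1 of 4, with 1.20, -0.09, -1.85 and -0.97 (3 of 4 without week 1). Myeloid genes were higher in DP for 5 of 12 members, including Lyz2 by 1.17 (adjusted p = 0.000238) and Apoe by 0.89 (adjusted p = 0.00206), T-cell identity genes were lower for 9 of 15 (median -0.76 at week 1 and -0.20, -0.08 and -0.08 at the later weeks; 4 lower and 2 higher without week 1), and epithelial Krt19 was higher by 1.47 (adjusted p = 0.00889), although it was lower in DP at week 2 (-0.43) and week 6 (-1.81).

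With an estimated correlation the chemokine receptor and integrin list kept its call (adjusted p = 0.0241). The circulating list did not (adjusted p = 0.0505 with an estimated correlation), nor did the resident list (adjusted p = 0.165), the NK-receptor list (adjusted p = 0.165), the immediate-early list (adjusted p = 0.296), the interferon list (adjusted p = 0.355), the myeloid list (adjusted p = 0.296) or the identity list (adjusted p = 0.181). Adjusted over the list alone, 16 circulating genes were lower, 13 resident genes higher, 8 NK-receptor genes higher, 13 immediate-early genes higher and 6 myeloid genes higher. Of all genes 2057 passed, 930 higher and 1127 lower, with a design-based count of 3648. The DN libraries carried other runs of library codes (46 to 75) than most DP libraries (5 to 42), so the run and the subset were nearly one: with the run as a term 98 genes passed, of which 9 were circulating genes, all lower. The list medians with that term were -1.30 for circulating (-1.33 without it), 0.63 for resident (0.42) and 0.67 for NK-receptor genes (0.72), so these medians stayed about as large while calls were lost. Inside codes 46 to 61 at weeks 2 and 6, 64 passed, with 16 higher and 48 lower.

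The comparison of SP with DN set CD69+ against CD69- cells within those sorted as CD103-. Itgae also differed, and the library code run nearly followed the subset (SP had 10 of 11 libraries in codes 5 to 42, DN 0 of 10). Circulating genes were again lower, in 15 of 19 members, with S1pr1 differing by -2.68 (adjusted p = 3.01e-06) and Lef1, a transcription factor of naive and memory cells, by -2.03 (adjusted p = 5.96e-06). Checkpoint genes were higher in SP for 13 of 22 members and lower for none, including Tnfrsf9, the activation receptor 4-1BB, by 0.97 (adjusted p = 0.000146), Havcr2, which encodes TIM-3, by 0.83 (adjusted p = 0.00123) and Nr4a2 by 1.28 (adjusted p = 0.0011). Both differences were small at week 1: the circulating medians were -0.13, -0.79, -1.67 and -1.90 and the checkpoint medians -0.06, 0.24, 0.95 and 1.01 at weeks 1, 2, 4 and 6. Csf1, a growth factor for macrophages, was higher by 1.58 (adjusted p = 1.32e-05), and Gzma was higher too (adjusted p = 0.000211). Proliferation genes were higher for 9 of 35 members, Mki67 by 0.49 (adjusted p = 0.00357), and Itgb7, the partner chain of CD103, was lower by a difference of -1.54 (adjusted p = 3.85e-05). Of the oxidative phosphorylation genes 4 of 23 were higher, Cox6c by 0.31 (adjusted p = 0.00578). That list rested mostly on week 1, with medians of 0.46 there and 0.07, 0.15 and 0.15 at weeks 2, 4 and 6, and the epithelial list moved with it, with medians of 3.35, -0.61, 0.28 and -1.62 at weeks 1, 2, 4 and 6. The oxidative list had 1 member higher without week 1, 0 with the library code run as a term, and Cox6c at -0.058 at week 2. Epithelial Krt19 was higher in SP by 1.64 (adjusted p = 0.00651) over the 4 weeks but differed by -1.75 at week 6. The circulating list (adjusted p = 0.0412), the chemokine receptor and integrin list (adjusted p = 0.0412) and the oxidative phosphorylation list (adjusted p = 0.0412) passed with an estimated correlation, whereas the checkpoint list (adjusted p = 0.146 with an estimated correlation) and the proliferation list (adjusted p = 0.474 with an estimated correlation) passed under the preset correlation. Adjusted over the list alone, 16 circulating genes were lower and 14 checkpoint and 11 proliferation genes higher. In all 2044 genes passed, 1165 higher and 879 lower, with a design-based count of 3679, and 62 passed with the library code run as a term. With that term the list medians were -1.43 for circulating (-1.05 without it), 0.65 for checkpoint (0.58) and 0.56 for resident genes (0.49), so these medians did not shrink.

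Tumor age was examined as week 6 against week 1 in each subset. In DP, cytotoxic genes rose in 9 of 15 members, including Fasl by 2.73 (adjusted p = 1.04e-09), Nkg7, a granule membrane protein, by 1.64 (adjusted p = 6.85e-06) and Tnfsf10, which encodes TRAIL, by 2.00 (adjusted p = 1.94e-05). Checkpoint genes rose in 18 of 22 members, Pdcd1 by 2.98 (adjusted p = 4.68e-06) and Cxcr6 by 2.05 (adjusted p = 1.91e-06), and resident memory genes in 13 of 26, Zfp683 by 2.95 (adjusted p = 3.89e-05). Proliferation genes rose in 23 of 35, with Mki67 up by 1.11 (adjusted p = 0.000407) and Mcm3 by 0.75 (adjusted p = 0.000176), and NK-receptor genes in 6 of 12, Klrd1 by 2.20 (adjusted p = 1.26e-05). Ccl5 rose by 2.19 (adjusted p = 3.36e-06), within 5 rising cytokine genes out of 15. T-cell identity genes rose with them, in 10 of 15 members, Cd8a by 1.63 (adjusted p = 5.53e-08). Epithelial genes fell in 5 of 8 members, Krt8 by -4.16 (adjusted p = 7.66e-05) and Krt18 by -3.27 (adjusted p = 0.000628). The mean epithelial score of the week 1 DP libraries was 2.27 (SD 0.19, n = 3) and that of week 6 was 0.07 (SD 0.29, n = 3), and the T-cell identity score was -0.77 and 0.01.

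With an estimated correlation the cytotoxic list kept its call (adjusted p = 0.0215). The checkpoint, identity, cytokine and epithelial lists each gave an adjusted p of 0.064 with an estimated correlation, the resident list 0.0817, the NK-receptor list 0.12 and the proliferation list 0.176. Adjustment over each list alone gave 12 cytotoxic, 18 checkpoint, 13 resident, 27 proliferation and 11 identity genes that rose and 6 epithelial genes that fell. Of all genes 1647 rose and 989 fell, 2636 together (1306 and 1193 after quantile normalization), with a design-based count of 4196. A fit of only the groups compared gave 583. The test used 1 shared spread, although the median SD over genes was 0.289 in DP at week 1 and 0.143 in DP at week 6. From week 2 to week 6, 26 genes differed in DP, and several genes that rose from week 1 had differences below 0, none of them called. Mki67 differed by -0.52, Mcm3 by -0.20, Zfp683 by -0.41, Tnfsf10 by -0.55, Klrd1 by -0.31 and Cd8a by -0.016. Their adjusted p in limma ran from 0.235 (Mki67) to 0.977 (Cd8a).

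In SP, 142 genes rose and 145 fell from week 1 to week 6, a total of 287 with a design-based count of 1380. Pdcd1 rose by 1.78 (adjusted p = 0.0106), Tox by 1.56 (adjusted p = 0.00161) and Cxcr6 by 1.58 (adjusted p = 0.00116), 3 of 4 checkpoint genes that rose out of 22, and Ccl5 rose by 1.47 (adjusted p = 0.00356). Circulating genes fell in 7 of 19 members, among them Satb1, a chromatin organizer of naive T cells (-1.53, adjusted p = 0.00161), and Sidt1 (-1.51, adjusted p = 0.00393). Krt8 fell by -3.21 (adjusted p = 0.0107), 1 of 3 epithelial genes that fell out of 8. The checkpoint, circulating and epithelial lists did not pass with an estimated correlation (adjusted p = 0.124, 0.192 and 0.192 with an estimated correlation), and 9 checkpoint, 7 circulating and 4 epithelial genes moved in those directions adjusted over the list alone. Without SP week 1 replicate 1, 2 or 3, 86, 111 and 146 genes passed, and without SP week 6 replicate 1, 2 or 3 there were 69, 102 and 93.

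In DN, epithelial genes rose from week 1 to week 6 in 7 of 8 members, among them the adhesion protein gene Epcam by 3.70 (adjusted p = 0.000586), Krt18 by 4.32 (adjusted p = 0.00238) and Krt19 by 4.38 (adjusted p = 0.00691). Vegfa, a hypoxia-induced angiogenic factor, rose by 3.57 (adjusted p = 0.000844), and Cox6c by 1.03 (adjusted p = 0.00138). Glycolysis and hypoxia genes rose in 5 of 24 members and ribosomal protein genes in 6 of 33. The epithelial list (adjusted p = 0.0919) and the ribosomal list (adjusted p = 0.407) did not keep their calls with an estimated correlation, and the glycolysis list missed the threshold under the preset one (adjusted p = 0.0541); adjusted over the list alone, 7 epithelial, 6 glycolysis and 10 ribosomal genes rose. In all 526 genes rose and 85 fell, 611 together with a design-based count of 1996, against a median of all genes that itself lay 0.12 above 0; after quantile normalization the split was 236 and 162, and after median rescaling 293 and 159. Each group had 2 libraries: without DN week 1 replicate 1, 71 genes passed and the adjusted p of Krt18 was 0.0799, without DN week 6 replicate 1, 160 passed, and without DN week 6 replicate 2, 137 passed and the adjusted p of Krt19 was 0.0518. With the library code run as a term limma called 0 genes, and 711 had an unadjusted p below 0.05. The epithelial median was then 2.60 (3.16 without the term) and 4 of its genes passed over the list alone, while the SE of Krt19 went from 0.89 to 1.41 and that of Epcam from 0.51 to 0.77.

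The change with tumor age differed between DP and SP in 857 genes, 580 with a more positive change in DP and 277 with a more negative one (design-based count 2304). A fit of only the groups compared gave 146. Proliferation genes made up 16 of the former out of 35 measured, with Mcm3 differing by 1.14 (adjusted p = 0.000594) and Mki67 by 1.40 (adjusted p = 0.00443). Interferon-stimulated genes made up 8 of 22, with Irf7 differing by 1.75 (adjusted p = 0.00134), and cytotoxic genes 7 of 15, Fasl by 1.58 (adjusted p = 0.000544) and Ctsw by 1.88 (adjusted p = 0.00128). The 3 lists did not pass with an estimated correlation (adjusted p = 0.204, 0.214 and 0.127 with an estimated correlation), and adjusted over the list alone 26, 14 and 8 of their genes differed. T-cell identity genes moved with them, 4 of 15 with a more positive change in DP (adjusted p = 0.378 with an estimated correlation). Their score went from -0.77 to 0.01 in DP and from -0.07 to 0.37 in SP. The epithelial score went from 2.27 to 0.07 in DP and from 1.75 to 0.25 in SP. Between weeks 2 and 6 limma called 0 genes for this difference, and 281 had an unadjusted p below 0.05.

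**Figure D3:**
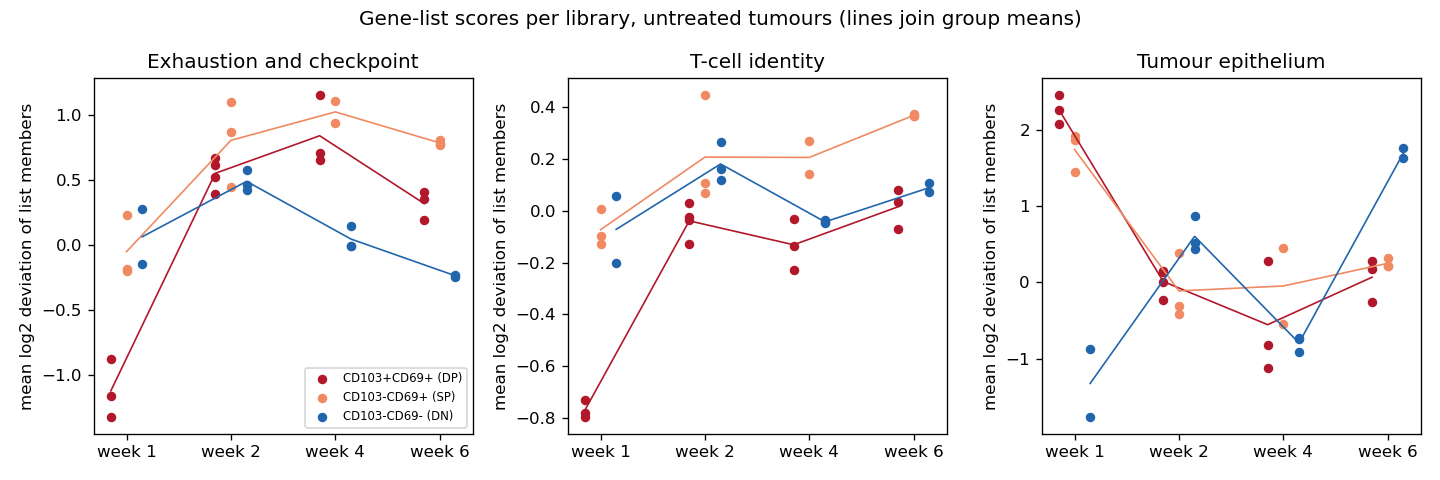
Mean score of gene lists in each tumor library by week and subset, where a score is the mean over list members of the log2 value minus the gene's mean over the untreated table. The epithelial score was 2.27 in DP and -1.33 in DN at week 1, and 0.07 in DP and 1.70 in DN at week 6.

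Spleen subsets served as circulating references. Against naive cells, the subset labelled EM had higher proliferation genes in 33 of 35 members, Mki67 by 4.24 (adjusted p = 2.29e-12) and Top2a by 3.19 (adjusted p = 8.36e-10). Cytotoxic genes were higher in 8 of 15 members and lower in 1, Fasl by 4.89 (adjusted p = 9.39e-15) and Gzma by 7.80 (adjusted p = 3.27e-11), and the chemokine gene Ccl5 by 7.75 (adjusted p = 4.34e-15). The transcription factor gene Zeb2 and the chemokine receptor gene Cx3cr1 were higher by 4.53 (adjusted p = 3.79e-11) and 4.33 (adjusted p = 8.36e-10), NK-receptor genes in 7 of 12 members, Klrc1 by 6.01 (adjusted p = 3.34e-10), checkpoint genes in 15 of 22, Pdcd1 by 3.46 (adjusted p = 1.99e-07), and the chemokine receptor gene Cxcr3 by 4.62 (adjusted p = 2.29e-12). Ribosomal protein genes were lower in 24 of 33 members, and TGF-beta response genes in 9 of 15, Skil, a feedback regulator of that pathway, by -1.38 (adjusted p = 8.51e-09). Markers of other lymphocytes rose with them: CD4 and regulatory T-cell genes were higher in 4 of 6 members (adjusted p = 0.0475 with an estimated correlation) and gamma-delta T, NK and NKT genes in 1 of 2. The proliferation (adjusted p = 0.0218), cytotoxic (adjusted p = 0.0218), NK-receptor (adjusted p = 0.0475) and TGF-beta (adjusted p = 0.0475) lists kept their calls with an estimated correlation, and the checkpoint (adjusted p = 0.074) and ribosomal (adjusted p = 0.0703) lists did not. Adjusted over the list alone, 34 proliferation, 8 cytotoxic, 8 NK-receptor and 15 checkpoint genes were higher and 26 ribosomal and 10 TGF-beta genes lower. In all 2601 genes passed, 1329 higher and 1272 lower (design-based 4011), and without EM replicate 1 or 3 or naive replicate 1 or 3 the count was 1720, 1596, 1728 and 1718.

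The subset labelled CM differed from naive cells in many of these lists. Proliferation genes were higher in 27 of 35 members, Mki67 by 2.78 (adjusted p = 3.82e-09), NK-receptor genes in 7 of 12, Klre1 by 5.57 (adjusted p = 4.97e-08), and cytotoxic genes in 7 of 15, Fasl by 4.07 (adjusted p = 6.7e-13). Both measured genes of the gamma-delta T, NK and NKT list were higher as well, Klrb1c by 3.87 (adjusted p = 0.00093) and Tcrg-C2 by 4.14 (adjusted p = 0.00267; 0.0795 for the list with an estimated correlation), and its mean score was 1.44 in CM and -2.57 in naive cells. Klrb1c is also a member of the NK-receptor list. Ccl5 was higher by 5.86 (adjusted p = 6.7e-13), and Ccr9, a gut-homing receptor, lower by a difference of -4.38 (adjusted p = 8.46e-07). The cytotoxic (adjusted p = 0.00894) and NK-receptor (adjusted p = 0.00961) lists kept their calls with an estimated correlation and the proliferation list did not (adjusted p = 0.0795); 9, 7 and 29 of their genes were higher adjusted over the list alone. There were 1986 genes, 1067 higher and 919 lower (design-based 3425), and 1178 and 1212 without naive replicate 1 or 3.

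Between the subsets labelled EM and CM, Zeb2 was higher in EM by 3.27 (adjusted p = 1.1e-07) and Cx3cr1 by 3.48 (adjusted p = 3.32e-07), proliferation genes were higher in 19 of 35 members, and interferon-stimulated genes lower in 13 of 22, Ifi44 by -3.35 (adjusted p = 0.000366). Markers of other cells went both ways. Epithelial genes were lower in 3 of 8 members, Krt8 by -4.08 (adjusted p = 0.000314), and myeloid genes in 4 of 12, the macrophage gene C1qb by -4.67 (adjusted p = 0.00152), with 1 myeloid, 1 B-cell and 1 CD4 or regulatory T-cell gene higher. The proliferation and interferon lists gave adjusted p = 0.232 each with an estimated correlation, and 23 and 15 genes adjusted over the list alone. There were 1626 genes, 867 higher and 759 lower (design-based 3166), and 853, 687, 920 and 868 without EM replicate 1 or 3 or CM replicate 2 or 3.

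Tumor cells were then set against the spleen EM subset, a contrast in which tissue and subset differ together. The spleens are titled as controls, so the condition of the source animals may differ as well. In DP, circulating genes were lower in 17 of 19 members, Cx3cr1 by -3.21 (adjusted p = 1.19e-08), and resident memory genes higher in 16 of 26, Litaf by 2.40 (adjusted p = 2.76e-09) and Isg20 by 2.24 (adjusted p = 2.34e-08). Glycolysis and hypoxia genes were higher in 18 of 24 members, including the glycolytic enzyme gene Tpi1 by 2.08 (adjusted p = 5.3e-09) and Vegfa by 3.43 (adjusted p = 3.2e-07). TGF-beta response genes were higher in 9 of 15 members, Pmepa1 by 2.70 (adjusted p = 1.19e-08), interferon-stimulated genes in 18 of 22, Isg15 by 1.99 (adjusted p = 5.63e-06), and immediate-early genes in 17 of 22, Egr1 by 1.71 (adjusted p = 1.57e-07). Epithelial genes were higher in 5 of 8 members, Krt8 by 4.96 (adjusted p = 4.32e-07), and B-cell genes lower in 6 of 6, Ighm by -1.84 (adjusted p = 3.81e-06). Macrophage genes were higher in 6 of 6 measured, 4 of them called, with a median of 1.34. Their camera adjusted p was 0.0165 with the preset and 0.779 with the estimated correlation. With an estimated correlation the circulating (adjusted p = 0.0278), resident (adjusted p = 0.0278), TGF-beta (adjusted p = 0.0278), glycolysis (adjusted p = 0.00384) and epithelial (adjusted p = 0.0393) lists kept their calls, and the interferon (adjusted p = 0.0642), B-cell (adjusted p = 0.0642) and immediate-early (adjusted p = 0.162) lists did not. Adjusted over the list alone, 17 circulating genes were lower, and 18 resident, 20 glycolysis, 11 TGF-beta, 19 interferon and 17 immediate-early genes higher. In all 3141 genes passed, 1453 higher and 1688 lower (design-based 4580), and 1875 and 1782 without EM replicate 1 or 3.

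DN cells, which lack both residency markers, also differed from spleen EM in these groups. Interferon-stimulated genes were higher in 20 of 22 members, Ifit3 by 2.00 (adjusted p = 2.47e-07), and glycolysis genes in 21 of 24, Aldoa by 1.29 (adjusted p = 2.77e-07). Resident memory genes were higher in 12 of 26, Skil by 1.43 (adjusted p = 3.92e-09), although Itgae was lower by a difference of -1.70 (adjusted p = 0.0113), a call lost without EM replicate 1 or 3 (adjusted p = 0.0526 and 0.0608). Zeb2 differed by -2.80 (adjusted p = 1.96e-08) and Krt8 by 4.95 (adjusted p = 1.64e-06). With an estimated correlation the interferon (adjusted p = 0.0459) and glycolysis (adjusted p = 0.00015) lists kept their calls and the resident list did not (adjusted p = 0.115); 21, 21 and 13 of their genes were higher adjusted over the list alone. There were 2180 genes, 1073 higher and 1107 lower (design-based 3815). The count was 946 and 835 without EM replicate 1 or 3, and 188 with the library code run as a term, under which the differences stayed about as large (Ifit3 1.85, Skil 1.33, Zeb2 -2.82, Krt8 5.24, and list medians of 1.19 for interferon and 0.81 for glycolysis genes against 1.20 and 0.82 without it).

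Of the 3 contrasts under ICB, DP against DN gave the most genes. Circulating genes were lower in DP for 15 of 20 members and higher for 2, with S1pr1 differing by -5.18 (adjusted p = 0.00306), Tcf7, a factor of memory and stem-like T cells, by -2.79 (adjusted p = 0.00306) and Lef1 by -3.04 (adjusted p = 0.00382). Gzma was higher by 4.58 (adjusted p = 0.00275), Gzmb by 2.43 (adjusted p = 0.00382) and Csf1 by 2.67 (adjusted p = 0.00306). Resident memory genes were higher in 13 of 26 members, Qpct by 1.71 (adjusted p = 0.00306), and interferon-stimulated genes in 16 of 23, Isg15 by 0.87 (adjusted p = 0.0137). Itgae was higher by 4.46 (adjusted p = 0.00477), a call lost without DN replicate 1 or 2 or DP replicate 1 or 3 (adjusted p between 0.0537 and 0.0698). Cd69 differed by 0.27 (adjusted p = 0.112), uncalled here but called in 3 of 15 alternatives. Ribosomal protein genes were lower in 17 of 33 members, and myeloid genes higher in 14 of 16, Lyz2 by 2.19 (adjusted p = 0.0163) and Csf1r, the receptor for Csf1, by 2.56 (adjusted p = 0.0109). The resident, circulating and interferon lists kept their calls with an estimated correlation (adjusted p = 0.0104 each); the myeloid (adjusted p = 0.234) and ribosomal (adjusted p = 0.11) lists did not. Adjusted over the list alone, 18 resident, 20 interferon and 15 myeloid genes were higher and 16 circulating and 29 ribosomal genes lower. In all 1008 genes passed, 601 higher and 407 lower (design-based 6101), with 617 and 670 without DN replicate 1 or 2, 2386 without DP replicate 3, and 120 or 103 with values below 0 or below 2 raised to that floor.

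SP against DN under ICB gave 515 genes, 332 higher and 183 lower (278 and 271 after quantile normalization; design-based 5217). S1pr1 differed by -4.53 (adjusted p = 0.00735), Klf2, the factor that drives S1pr1, by -3.09 (adjusted p = 0.00795) and Tcf7 by -2.50 (adjusted p = 0.00782), within 13 lower circulating genes out of 20. Checkpoint genes were higher in 9 of 22 members, Pdcd1 by 1.15 (adjusted p = 0.0081), and resident memory genes in 13 of 26, Osgin1 by 1.61 (adjusted p = 0.00794). Markers of other cells were higher too. Macrophage genes were higher in 10 of 10 measured, with a median of 1.05, 0 past limma's test and 7 adjusted over the list alone. Their camera adjusted p was 0.00411 with the preset and 0.779 with the estimated correlation. Epithelial scores ran from 0.43 to 0.90 in SP and from -1.19 to -1.05 in DN libraries, and stroma scores from 0.30 to 0.59 and from -1.33 to -1.31. Itgae was higher by 2.11 (adjusted p = 0.0283), a call lost without DN replicate 1 or 2 or SP replicate 1 (adjusted p between 0.184 and 0.276). The circulating (adjusted p = 0.0224) and resident (adjusted p = 0.03) lists kept their calls with an estimated correlation and the checkpoint list did not (adjusted p = 0.146); 14, 18 and 14 of their genes differed that way adjusted over the list alone. Without SP replicate 1 the count was 1438. With values below 0 or 2 raised to that floor limma called 0 genes, and 2951 or 2911 had an unadjusted p below 0.05.

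**Figure D4:**
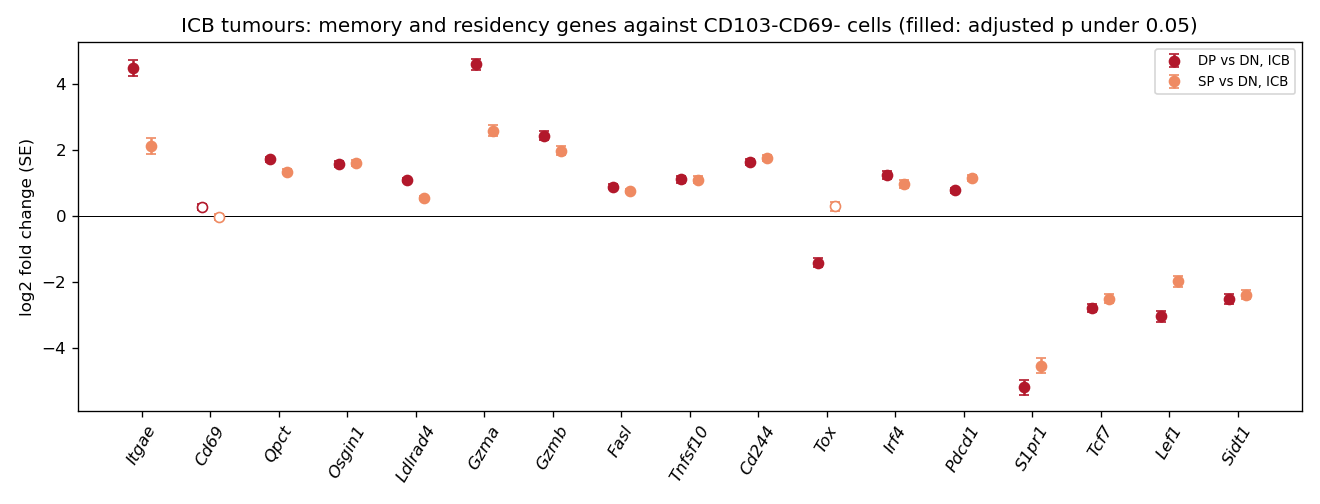
Log2 differences with standard errors for genes of the ICB table, for DP against DN and SP against DN. Itgae was 4.46 and Gzma 4.58 higher in DP than in DN, and S1pr1 differed by -5.18.

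DP and SP under ICB differed in 5 genes, 1 higher and 4 lower in DP (design-based 3250; 1733 with an unadjusted p below 0.05). Simulated tables of this shape gave 0.8 false calls per table at the same degrees of freedom, and 13.2 where unwanted factors had been added before removal, so 5 calls do not exceed what that setting gives by chance. Ifitm1, an interferon-induced membrane protein gene, was higher by 0.95 (adjusted p = 0.0432), and Tox differed by -1.69 (adjusted p = 0.0432). The other 3 were Atp2b2 (-5.38), Tmprss6 (-3.06) and Trav10d (-3.62), named after their values were seen. Itgae differed by 2.35 (adjusted p = 0.0849), uncalled here but called in 4 of 16 alternatives. The checkpoint list was lower as a set, with 1 of 22 members past the test, 11 adjusted over the list alone and a median of -0.36 (adjusted p = 6.83e-06, but adjusted p = 0.279 with an estimated correlation). Interferon-stimulated genes had a median of 0.21 and kept their call with an estimated correlation (adjusted p = 0.0294), with 0 of 23 members past limma's test and 1 adjusted over the list alone. The myeloid median was 1.25, with 0 of 16 members past the test, 14 adjusted over the list alone and an adjusted p of 0.293 with an estimated correlation. Leaving out DP replicate 1, 2 or 3 gave 180, 97 and 682 genes, and leaving out SP replicate 1 or 3 gave 371 and 3; the call for Tox was lost without SP replicate 2 (adjusted p = 0.0809) and those for Ifitm1, Tmprss6 and Trav10d without SP replicate 3 (adjusted p = 0.0629, 0.0603 and 0.0771). With values below 0 or 2 raised to that floor limma called 0 genes, with 1675 and 1733 at an unadjusted p below 0.05.

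Subset differences were compared between the untreated and ICB tables across the 10187 genes measured in both, which are not independent replicates. The DP to SP differences correlated weakly, with Pearson's r of 0.208 and Spearman's rho of 0.176. Of the 363 shared genes called between DP and SP without treatment, 272 (74.9%) had the same sign under ICB, against 56.7% of all shared genes. For DP against DN r was 0.337, and 337 genes were called in both tables, 286 of them in the same direction: 147 higher where independent lists would share 45.8, and 139 lower where they would share 33.8. For SP against DN r was 0.304, with 224 genes called in both and 211 in the same direction.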

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

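The test of the DN against the DP change with tumor age, and the tests of cytotoxic, checkpoint and proliferation genes against T-cell identity genes, were chosen only after the week results had been seen.

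The change from week 1 to week 6 differed between DP and SP in 857 genes by an interaction test (146 in a fit of only the groups compared). It also differed between DN and DP: 7 of the 8 epithelial genes had a more positive change in DN, Krt18 by 7.59, Krt8 by 7.05 and Krt19 by 6.99, with Krt5 the exception (2.16, adjusted p = 0.101). All 8 passed when adjusted over the list alone, the list's median was 5.37, and the camera p was 3.65e-09 with a preset and 0.00231 with an estimated correlation. Over all genes measured, 1910 differed in this way, 1077 with a more positive change in DN and 833 with a more negative one.

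A technical account of the DP change is that tumor-cell RNA diluted T-cell RNA at week 1, when the epithelial score was highest in DP, so that T-cell genes rose alike afterwards. Cytotoxic genes rose by 0.66 more than identity genes (permutation p over genes 0.0101, two-sided, 100000 resamples), checkpoint genes by 0.66 more (p = 0.00849) and proliferation genes, which dividing tumor cells express too and which therefore do not bear on dilution, by 0.11 more (p = 0.422). The smallest of these p-values after adjustment over the 3 lists was 0.0152, which argues against dilution as the whole cause of the cytotoxic and checkpoint rises; permuting genes treats them as independent, which makes the p too small. With the library code run as a term 2257 genes still differed with week in DP, which argues against the run as the whole cause there; in DN, where the libraries of weeks 1 and 6 lie in different runs and the run is known apart from week through week 4 alone, limma called 0 genes with the term (711 unadjusted) while the epithelial median stayed at 2.60 (3.16 without it), so the run was neither excluded nor shown as the cause. A change of the DP cells with tumor age and a change of sort purity were not separated, since no control for purity was used here.

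Within DP at week 2, a group of 4 libraries, 2 of 25 tested items had 1 library apart from the rest: the circulating memory score in replicate 2, whose gap was 0.833 of the group's range, and the lipid score in replicate 4, at 0.849. The lipid score was -0.073 in replicate 4 and -0.033, -0.026 and -0.027 in replicates 1, 2 and 3, a small gap. About 1 item in 20 would stand apart in this way by chance if the 4 values were independent and normal. The table lacks 10 directions, so that rate may not hold here. No explanation was tested for either.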

How the results depend on the processing

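The alternatives chosen only after the data had been seen were design-based degrees of freedom, the fits without week 1, week 6 against week 2, and DP against DN within codes 46 to 61; the others were planned. A count was taken to have moved when it changed by more than 1.5 times. The cause of these changes was not tested. A count tool could not be tried in place of limma, since whole reads cannot be recovered from the deposited values. Where a library left out leaves a group with 1, that lone sample is assumed to vary like the other groups. Counts of genes came from 15 comparisons and are given below where they moved.

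With design-based degrees of freedom the counts rose to 1554 for DP against SP, 3648 for DP against DN and 3679 for SP against DN, to 4196 for DP, 1380 for SP and 1996 for DN between weeks 6 and 1, and to 2304 for the interaction. They were 4011 for EM against naive, 3425 for CM against naive, 3166 for EM against CM and 3815 for DN against EM, and under ICB 3250, 6101 and 5217 (DP against SP, DP against DN and SP against DN, the order used throughout). With array weights DP against SP gave 579, SP by week 1898, DN by week 216, EM against naive 8596, CM against naive 8225, EM against CM 10041, DP against EM 7786, DN against EM 6536 and ICB 128, 9334 and 2019. Such weights favor libraries close to their group mean. The root mean square deviation was 0.038 for CM replicate 2, against 0.265 and 0.240 for CM replicates 1 and 3. As the deposited values lack spread within groups, 10041 of 10560 genes is not a credible number of differences. With a minimum of a 2-fold change the untreated pairs gave 16, 183 and 245 genes, DP, SP and DN by week 881, 119 and 373, the interaction 459, EM against naive 1306, CM against naive 843, EM against CM 641, DP and DN against EM 837 and 595, and DP and SP against DN under ICB 498 and 235.

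Except for the design-based counts, every alternative kept the full table's factor for degrees of freedom, 0.6429 or 0.4. The rank was not found anew for any of them, so their counts are not strictly like the main ones. Fits of only the groups compared gave 191 for DP against SP, 583, 559 and 392 for DP, SP and DN by week, 146 for the interaction, 1209 for EM against naive, 756 for EM against CM, 1041 for DN against EM, and 206, 4315 and 1331 under ICB. With the library code run as a term DP against DN fell to 98, SP against DN to 62, DN against EM to 188 and DN by week to 0 in limma. For DN by week 711 had an unadjusted p below 0.05, and the design-based count without the term was 1996. The medians of the lists that carried these differences were larger, about as large or somewhat smaller with the term. Circulating genes gave -1.30 against -1.33 for DP against DN and -1.43 against -1.05 for SP against DN. Interferon genes gave 1.19 against 1.20 for DN against EM, and epithelial genes 2.60 against 3.16 for DN by week. Within codes 46 to 61 DP against DN gave 64. Without week 1, DP against SP gave 44. Between weeks 6 and 2 DP gave 26, SP 68 and DN 76, and the interaction gave 0 in limma (281 with an unadjusted p below 0.05). Weeks alone gave, for DP against SP, 1835 at week 1, 0 at week 2 (677 unadjusted), 15 at week 4 and 0 at week 6 (729 unadjusted), for DP against DN 86 at week 2 and 338 at week 6, and for SP against DN 767, 49 and 319 at weeks 1, 2 and 6. Quantile normalization gave 398 for DN by week and median rescaling 8 for DP against SP under ICB. Values below 0 raised to 0 gave limma counts of 0 (1675 unadjusted), 120 and 0 (2951 unadjusted) under ICB, and values below 2 raised to 2 gave 0 (1733 unadjusted), 103 and 0 (2911 unadjusted). Of 345 list tests 161 passed with the preset and 32 with the estimated correlation.

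With a replicate block, in which libraries of the same number are treated as a pairing, DP against SP gave 163 genes, and the ICB pairs 628, 1721 and 1213. Residuals of same-numbered libraries correlated between -0.99 and 0.92 over 46 pairs, with 13 above 0.1, so the numbers were not taken to pair samples. Both ends of that range came from ICB, where residuals of rank 2 favor extreme correlations. Between DP and SP of the untreated tumor all 11 such pairs correlated positively, from 0.0097 to 0.861, with 5 above 0.1. The highest joined replicate 1 of DP and of SP at week 4, where SP had 2 libraries with mirrored residuals. The other SP library, whose code follows that of the DP library, therefore gave -0.861. Of the DP libraries 8 were closest to the SP library of their own number, a hint of shared handling. Several of these pairs also have consecutive library codes in the labels, although no label names a pairing. In the spleen and under ICB some neighboring codes carry different replicate numbers, so the check by number could not exclude a pairing.

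Leaving out each library in turn gave 263 to 424 genes for DP against SP, 1655 to 2212 for DP against DN and 1555 to 2070 for SP against DN. DP by week ran from 1872 to 2449, SP by week from 69 (without week 6 replicate 1) to 146, DN by week from 71 (without week 1 replicate 1) to 794, and the interaction from 578 to 1010. The range was 1596 to 2843 for EM against naive, 1178 to 2037 for CM against naive, 687 to 1863 for EM against CM, 1782 to 3336 for DP against EM and 835 to 2282 for DN against EM; the lowest value came without EM replicate 3 in 4 of these and without naive replicate 1 for CM against naive. Under ICB the ranges were 3 to 682, 617 to 2386 and 397 to 1438. The correlation of DP to SP differences between the tables, 0.208, ran from 0.185 to 0.225 when a library was left out.

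Of 906 calls among genes the naming rule took, 204 (22.5%) were lost on leaving out some library. The 148 gene results printed were picked with that outcome known (10 of 145 calls lost), so their share does not measure stability. Over the alternatives, the printed gene results stayed on the same side of the threshold 3363 times and gained a call 7 times. They lost a call 252 times with the same sign and 20 times with a change of sign. Changes of sign in results never called were not counted, such as Cd69 in DP against SP, from -0.62 to 0.54. With floors raised to 0 and 2, 8 and 17 of them had no value because the compared libraries lay at the floor. Signs changed between weeks 6 and 2 in DP for Zfp683 (-0.41), Tnfsf10 (-0.55), Klrd1 (-0.31), Mcm3 (-0.20), Mki67 (-0.52), Cpt1a (0.29), Acadl (0.077) and Cd8a (-0.016), in DN for Cox6c (-0.14), and in the interaction for Mki67 (-0.073). At week 1 alone they changed for Hba-a2 in DP against SP (1.06) and, in DP against DN, for Zfp683 (-1.18), Gzma (-0.064), Ikzf2 (-1.06) and Il2ra (-0.75). Krt19 in DP against DN was -0.43 at week 2, -1.81 at week 6 and -1.61 within codes 46 to 61, Krt19 in SP against DN was -1.75 at week 6, and Cox6c in SP against DN was -0.058 at week 2.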

Other observations

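The tests of macrophage genes, of dendritic against myeloid genes, of checkpoint against identity genes and of the rank of residuals in other splits were chosen only after the list results had been seen, and the value above which the simulated share was taken to be high was set after that share was known.

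Several lists held few called genes. In DP, lipid uptake and oxidation genes fell from week 1 to week 6 in 3 of 11 members, Cpt1a by -0.89 (adjusted p = 0.000339) and Acadl by -0.75 (adjusted p = 0.00115), although the list did not pass with an estimated correlation (adjusted p = 0.112). Between weeks 6 and 2 both differences were positive, 0.29 and 0.077, and neither was called (adjusted p = 0.414 and 0.868). CD4 and regulatory T-cell genes were higher in DP than DN for 3 of 6 members in the untreated tumor, with Ikzf2, a regulatory T-cell factor, higher by 1.12 (adjusted p = 0.00185) and the interleukin-2 receptor gene Il2ra by 0.57 (adjusted p = 0.0102); both were lower in DP at week 1 alone (-1.06 and -0.75), and the list's adjusted p was 0.255 with an estimated correlation. Under ICB the same list was higher in DP for 3 of 7 members, Foxp3 by 3.34 (adjusted p = 0.0197) and Il2ra by 2.22 (adjusted p = 0.00987), with 0.268 for the list. Stroma and endothelium genes were higher in DP than DN under ICB for 2 of 9 members, Cdh5 by 3.27 (adjusted p = 0.00382) and Sparc by 2.05 (adjusted p = 0.0178), with 0.214 for the list. Of the gamma-delta T, NK and NKT list, Tcrg-C2 was higher in DP than DN under ICB by 1.33 (adjusted p = 0.0168), with 0.231 for the list. Both erythroid genes were lower in DP than SP in the untreated tumor, Hba-a2 by -2.55 (adjusted p = 0.0097), but Hba-a2 was higher at week 1 alone (1.06).

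Myeloid genes were higher in DP than SP in both tables. T-cell identity genes were lower in the untreated table (mean -0.41, SD 0.145 over 15 genes), but under ICB their mean was -0.06 (SD 0.206). Macrophages or monocytes among the DP cells are a candidate explanation of the myeloid difference, although a CD8 gate should remove them. The medians of the macrophage list were 0.444 in the untreated table (6 of 12 genes measured, 6 higher) and 1.19 under ICB (10 of 12 measured, 10 higher), but all 12 genes are members of the myeloid list, so these values restate the pattern and decide nothing. Under ICB the means in DP, SP and DN were 8.78, 7.52 and 6.59 for Lyz2 and 8.04, 6.91 and 5.99 for Apoe. Genes of CD103+ dendritic cells, which share no gene with any list, had medians of 0.062 and 0.239. These lay below the myeloid medians by 1.53 and 1.58 SDs over the dendritic genes, a distance over genes that is not a test. Members went both ways, with 6 of 10 and 6 of 12 measured higher in DP. MHC class II genes, 4 of 7 shared with the myeloid list, were higher in 6 of 6 and 7 of 7 measured, with medians of 0.477 and 1.25. These values do not decide whether dendritic cells were a source of the rise. A lower share of T-cell RNA would lower checkpoint and identity genes alike. They differed by -0.09 in the untreated table (p = 0.361, permutation of genes between the 22 checkpoint and 15 identity genes). Under ICB checkpoint genes were lower by a further -0.43 (p = 0.0015 by the same permutation). Since identity genes hardly fell there, this argues only against that share as the whole cause of the lower checkpoint genes under ICB.

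The number of genes under ICB may owe much to the authors' normalization. In simulated tables of that shape, with directions removed in the way the deposited table lacks them, 24.2% of unchanged genes had p below 0.05 at design-based degrees of freedom, and 1216 were falsely called per table, against 3250 called in DP against SP under ICB. Where unwanted factors had been added before removal, the share was 38.5% and the false calls 3392, more than were observed. This is why counts with reduced degrees of freedom were reported.

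Other splits of the same libraries into groups of the same sizes were tried where both groups had 3 or more. For DP against SP, 1 of 100 splits, the real one with 368, gave as many genes, and the highest of the others gave 148. The same 1 of 100 held for DP against DN (2057, highest other 594), SP against DN (2044, highest other 216), the interaction (857, highest other 401), DP against EM (3141, highest other 229) and DN against EM (2180, highest other 636). With 3 libraries against 3 the 10 splits were too few to tell: DP by week gave 2636 (highest other 0), SP by week 287 (highest other 0), EM against naive 2601 (highest other 1), CM against naive 1986 (highest other 19), EM against CM 1626 (highest other 0) and DP against SP under ICB 5 (highest other 0). These splits favor the real one: the residuals from the real groups had a rank of 18 in the untreated table and 2 in that of ICB, and those from every other split tried had 19 to 22 and 3, so the deposited values lack spread within the real groups that they keep in other splits. Chance was therefore not excluded by these counts alone. DN by week and the DN comparisons under ICB, with groups of 2, were not split.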
